A study of Homo sapiens with 111 samples.

How the data were processed

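Total RNA from 111 AML samples was extracted with Trizol, labelled with biotin and hybridized to Affymetrix U133A arrays, per the labels' protocols, which say that samples were cryopreserved blood or marrow. The deposited values are linear MAS5 signal intensity values, per the submitters' processing notes, which name MAS5. Its version, its parameters and the probe set description used are not given in the sources used here. Over the 22283 deposited probe sets, values ran from 0.2 to 235311.3, with a median of 217.7. The mean signal of each array, with 2% of the values trimmed at each end, lay near 500, so the arrays were taken as scaled to that target and not log transformed.

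Samples were grouped by the code in their titles into AE, i16, PML, MLL, M7, misc and N. The lists, the comparisons, the tests, the filter, the rule for naming genes and all alternatives but 4 were chosen before the data were examined. From the deposited intensity, log2(signal + 44) was computed, 44 being 20% of the median of all values, with no further normalization. Probe sets were named through the array's annotation: 19065 had 1 gene symbol, 1043 several and 2107 none, besides 68 control probe sets. Gene identifiers of 19053 probe sets matched a gene table of assembly GRCh38.p14, and 0 symbols changed. Probe sets with several symbols or none, control probe sets, XIST, TSIX and genes of the Y chromosome were not tested. A probe set was kept if it lay above its array's median signal on at least 7 arrays, which 13881 of 19034 did. For each gene the kept probe set with the highest mean stood for it, leaving out cross-hybridizing _x_at probe sets where another existed. This gave 9369 tested genes of 11939 with a usable probe set, 437 of them through an _x_at probe set, and 3009 had more than 1 kept probe set.

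Genes were tested with limma 3.58.1 in R 4.3.3 (files read with the data.table package, version 1.17.8) in a model with 1 mean per group over all 111 arrays. Each contrast was a group's mean minus the unweighted mean of the other 6 groups, or AE minus i16, or misc minus N, and the moderated F test asked for any difference among the 7 groups. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Lists were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over the 140 tests of the 7 groups, and over 20 tests in each direct comparison. Camera with a correlation estimated for each list and fry, a test of whether the genes of a list move one way on balance, were alternatives.

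The 21 fixed lists were fusion partner genes, HOXA cluster, HOXB cluster, TALE homeobox cofactors, stem and progenitor markers, myeloid transcription factors, azurophil granule, late neutrophil, monocyte, megakaryocyte and platelet, erythroid, T and NK cell, B cell, stromal, HLA class II, HLA class I and antigen processing, proliferation, interferon response, immediate early, inflammatory chemokine and cytokine, and coagulation and fibrinolysis genes. The HOXA list could not be tested, since 0 of its 11 members had a named probe set that passed the filter. RUNX1, MLLT1 and AFDN (listed as MLLT4) of the fusion partners were not tested either.

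Genes named in the text had to be called and to have a group median above, or below, the median of each other group compared. By this rule the 10 largest rises and 6 largest falls were named for AE, i16, PML, MLL and M7, the 6 and 4 largest for misc and N, and the 5 and 5 largest for each direct comparison. The rule also named the measured fusion partners and, of other lists, the 2 to 4 called members with the largest change where a list is described. Members of lists with a smaller change, and those named for lists that were not called, such as MEIS1, PBX3, TAL1, GATA2, F3, TFPI, SPARC, HOXB2 and CEBPA, were chosen after their values were seen.

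Alternatives were a pseudocount of 1 or of the median of all values, quantile normalization, scaling to a common median, no filter or a stricter filter at the 75th percentile, the most variable probe set per gene, every probe set, a variance trend with robust fitting, estimated array weights, all other arrays pooled as the reference, a reference without misc, the 3' to 5' ratio of GAPDH and ACTB as a covariate, the T and NK cell and erythroid list means as covariates, and a replicate block on the number in the titles. Added after the data were seen were leaving out the 10 arrays that stood apart, fits of each set of 4 of the 7 PML arrays, list tests with each array left out in turn, and leaving out the 2 arrays whose MYH11 and CBFB both lay on the wrong side of the midpoint between the i16 median and that of the other groups' medians. Pooling the other arrays changed the weights of the reference and also counted the differences among the other groups as spread. The procedure was tested on simulated data of 9369 genes with known changes. In the PML comparison 25.4% of genes changed by 0.5 log2 were recovered, 71.6% at 1 and 98.5% at 2, with 7.8% of the calls false. In the AE comparison 68.7%, 97% and 100% were recovered at these sizes, and 3.28% of the calls were false. The simulated genes varied independently, with the same spread in every group and no arrays that stood apart. These rates may therefore not hold for the real arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.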

Results

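RNA from 111 samples of acute myeloid leukemia (AML) in children, was measured on Affymetrix U133A arrays, with 1 array per sample. The series and sample titles place all samples at diagnosis, while the growth protocol also names remission, and whether any sample was taken in remission is not given in the sources used here. The sample titles sort the arrays into 7 groups: AE (20 arrays), i16 (16), PML (7), MLL (15), M7 (9), misc (23) and N (21). The labels do not spell out these codes. From knowledge of the field, AE was read as the AML1-ETO (RUNX1-RUNX1T1) fusion, i16 as the chromosome 16 inversion that joins CBFB to MYH11, and PML as the PML-RARA fusion of promyelocytic leukemia. MLL was read as a rearranged MLL (KMT2A) gene, M7 as megakaryoblastic leukemia, misc as miscellaneous and N as a normal karyotype. The samples were cryopreserved blood or marrow, and which of these each sample was is not given in the sources used here. The labels do not state that each sample came from a different person, so the p-values below measure the spread between these samples. The number of arrays in each group limits the precision.

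The median signal per array ran from 162 to 302, with a median of 216. The median correlation of an array with the other arrays had a median of 0.829 and ran from 0.685 to 0.867. By a low correlation or a high ratio of the 3' to the 5' control probe sets of GAPDH, 10 of the 111 arrays stood apart, of which 3 were among the 7 PML arrays, 2 each in AE, i16 and M7, and 1 in misc.

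The comparisons ask which genes mark each group of leukemias. Each group was set against the unweighted mean of the other 6 groups, and AE was compared with i16 and misc with N. Of 9369 genes tested with limma, 4083 (43.6%) differed among the 7 groups by the moderated F test at an adjusted p under 0.05. Values after ± are standard errors of a log2 fold change unless SD is written, and adjusted p-values of genes are over all genes tested. Gene lists fixed before the data were examined were tested with camera, which asks whether a list shifts relative to the other genes. Of 140 tests of 20 lists in 7 groups, 50 were called, 25 up and 25 down, and 1 of the 50 was kept with an estimated correlation between genes, that of the HOXB cluster in misc.

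**Figure D1:**
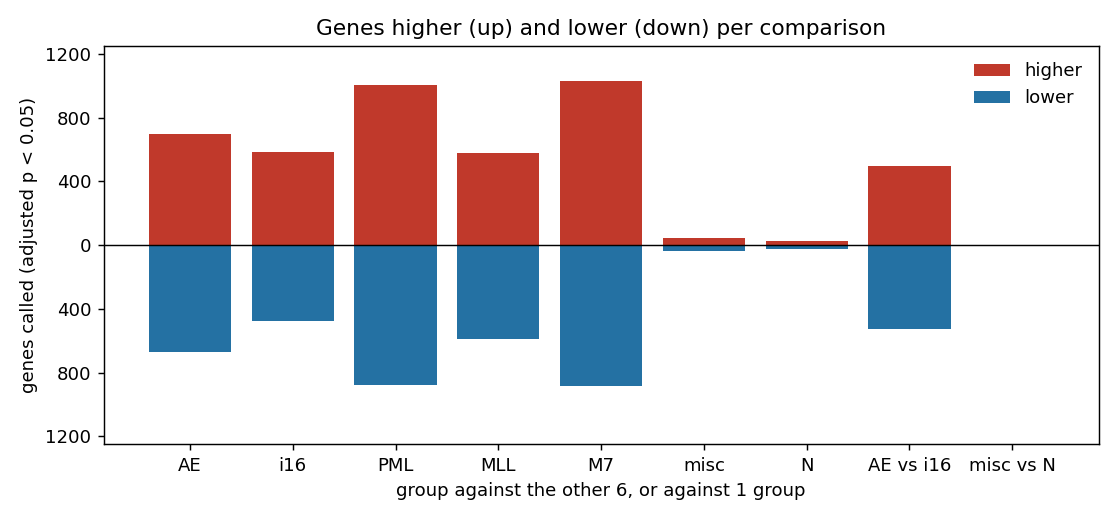
Number of genes called at an adjusted p under 0.05 (y axis), higher as upward bars and lower as downward bars, for each group against the other 6 and for AE against i16 and misc against N (x axis). M7 had 1030 higher and 886 lower genes, N had 24 and 27, and misc against N had 0.

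AE samples carried high RUNX1T1, the partner of RUNX1 in the fusion that the code was read to name. With 1 of its 4 probe sets, chosen after the values were seen, RUNX1T1 was 3.75 ± 0.14 higher on the log2 scale than in the other groups. With it, 20 of 20 AE arrays lay above every array of the other groups. The median signal of this probe set was 1130 in AE and 18.4, near background, on the other arrays, so the size of the change is set in part by the pseudocount (5.43 with 1, and 2.26 with the median of all values). The other RUNX1T1 probe sets gave 3.88, 2.55 and 1.19, the last being the one with the highest mean on the log2 scale, which stood for the gene in the test (adjusted p = 2.4e-13). POU4F1, a homeobox transcription factor of sensory neurons, was 4.38 ± 0.27 higher (adjusted p = 1.7e-26, mean 12.25 ± 1.56 SD, n = 20). TRH, the precursor of thyrotropin-releasing hormone, was 4.42 ± 0.38 higher (adjusted p = 3.1e-17), and ROBO1, a guidance receptor, 3.34 ± 0.23 higher. Other genes that ranked highest were PRAME, a tumor antigen (2.73 ± 0.28), MAN1A1, a Golgi mannosidase (2.66 ± 0.31), HPGDS, a prostaglandin D synthase of mast cells and other hematopoietic cells (2.63 ± 0.36), BAALC (2.58 ± 0.27) and CACNA2D2, a calcium channel subunit (2.48 ± 0.22). The mast cell tryptase genes TPSAB1 (2.70 ± 0.44) and TPSB2 (2.59 ± 0.43) are near-identical copies read by cross-hybridizing probe sets, so which of them rose is uncertain. Without the filter on dim probe sets, another TPSAB1 probe set took its place and gave 0.09. SPINK2, a protease inhibitor of progenitor cells, fell by 3.00 ± 0.47 (log2). Other large falls were those of CTSW, a protease of cytotoxic cells (-2.71 ± 0.34), the adaptor LAT2 (-2.61 ± 0.20, and -0.06 in its other probe set), the actin-capping gene CAPG (-2.55 ± 0.24), CPVL, a carboxypeptidase of macrophages (-2.43 ± 0.33), and ALDH2, an aldehyde dehydrogenase (-2.16 ± 0.29).

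The HLA class II genes, which present antigen to helper T cells, were higher in AE, with 10 of 12 tested members called higher and 12 when adjusted over the list alone. Among them were HLA-DPA1 (1.74 ± 0.38), HLA-DRA (1.53 ± 0.35) and CIITA, the class II activator (1.45 ± 0.24). The list was called by camera (adjusted p = 8.74e-09, but adjusted p = 0.14 with an estimated correlation). Of 17 stem and progenitor markers 7 rose and 1 fell (8 and 1 adjusted over the list alone), with NPR3 at 2.33 ± 0.29, CD34 at 2.14 ± 0.32 and KIT, the stem cell factor receptor, at 1.47 ± 0.34. This list was called up (adjusted p = 2.95e-04, but adjusted p = 0.288 with an estimated correlation). Of 17 megakaryocyte and platelet genes 5 fell (6 adjusted over the list alone), among them ITGA2B (-1.53 ± 0.20) and GFI1B (-1.49 ± 0.26), with a list adjusted p = 3.75e-05 and an adjusted p = 0.0877 with an estimated correlation. Of 22 proliferation genes 8 fell, such as BIRC5 (-0.64 ± 0.16) and MKI67 (-0.51 ± 0.14), and adjusted over the list alone 15 fell and 1 rose. That list had an adjusted p = 1.12e-05 and an adjusted p = 0.547 with an estimated correlation. Of 14 monocyte genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with LILRB2 at -1.42 ± 0.38, FCN1 at -1.25 ± 0.44 and TLR2 at 1.04 ± 0.26. As a list, monocyte genes had an adjusted p = 0.0019, and an adjusted p = 0.586 with an estimated correlation. The azurophil granule genes, which encode the enzymes of the primary granules of neutrophils, moved apart: 4 of 12 rose, among them ELANE (2.45 ± 0.42), PRTN3 (2.23 ± 0.47) and MPO (2.14 ± 0.42), and 4 fell, among them CTSG (-2.10 ± 0.44). The counts adjusted over the list alone were also 4 and 4, and the list was not called (adjusted p = 0.641). The references for MPO and ELANE hold M7, at means of 9.26 and 7.8. The homeobox gene MEIS1 (-1.72 ± 0.27) and its partner PBX3 (-0.98 ± 0.28) were lower.

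In all, 696 genes were higher and 673 lower in AE, of which 127 and 113 by at least 2-fold. With arrays scaled to a common median the split was 467 higher and 845 lower. The HOXB cluster (2 of 7 lower, 5 adjusted over the list alone, median -0.49) and the late neutrophil genes (2 of 13 higher, also 2 adjusted over the list alone, median 0.52) were each called at an adjusted p = 0.0461, with adjusted p = 0.573 and adjusted p = 0.753 with an estimated correlation, and both calls ended with quantile normalization. Without 1 AE array the late neutrophil median fell to 0.25 and the list was not called by camera (adjusted p = 0.449). KMT2A was 0.56 ± 0.11 higher and MYH11 -0.73 ± 0.15 lower, calls that ended with the most variable KMT2A probe set (0.42) and with all other arrays pooled as the reference (-0.63). The reference for MYH11 holds i16, at a mean of 9.28.

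**Figure D2:**
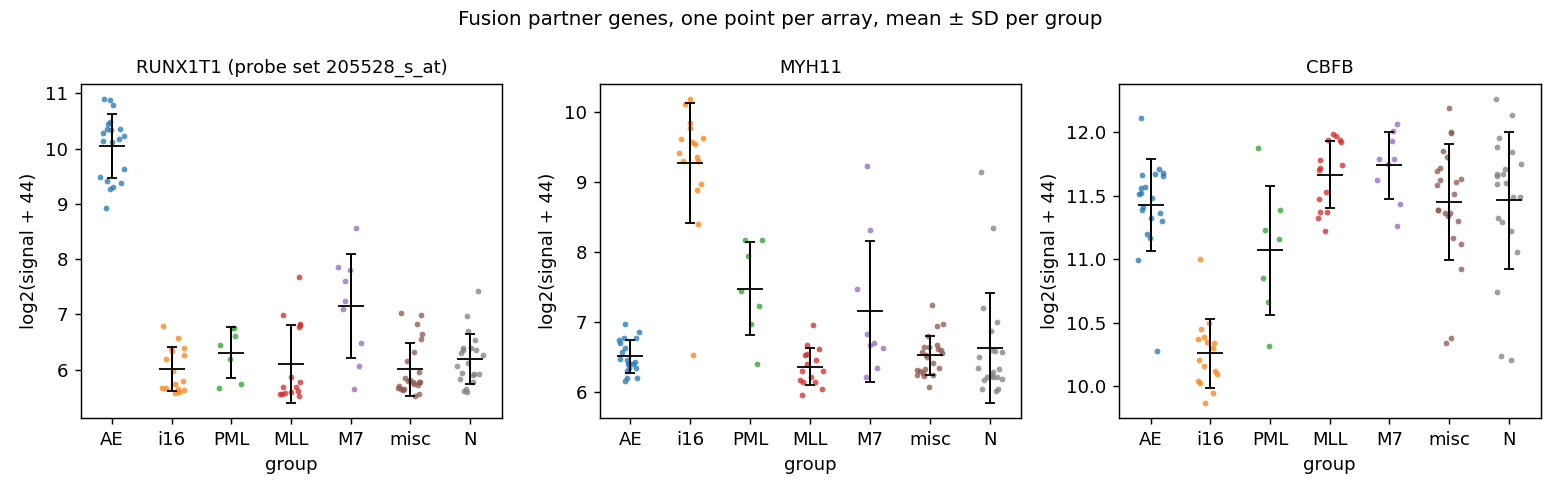
Level of RUNX1T1, MYH11 and CBFB, genes that join in fusions of AE or i16 (y axis, log2 of signal plus 44), with 1 point per array by group (x axis) and mean ± SD as bars. All 20 AE arrays lie above every other array for this RUNX1T1 probe set, and 12 of 16 i16 arrays lie above every other array for MYH11.

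As a group, i16 carried high MYH11, a smooth muscle myosin gene and the fusion partner of CBFB, at 2.50 ± 0.16 above the other groups (adjusted p = 1.1e-24, mean 9.28 ± 0.86 SD, n = 16), and 12 of 16 i16 arrays lay above all arrays of the other groups and 15 above the median of each. CBFB, the other partner and a subunit of the core-binding factor, was lower, at -1.21 ± 0.11 (adjusted p = 3.8e-15), with -0.78 in its other probe set. With both MYH11 and CBFB on the wrong side of the midpoint between i16 and the other groups, 2 of 111 arrays did not match their group's label, 1 in i16 and 1 in N. MSLN, a surface protein of mesothelium, was 3.77 ± 0.47 higher (adjusted p = 1.3e-09), followed by the zinc finger gene ST18 (2.89 ± 0.33), the lectin gene LGALS2 (2.86 ± 0.43), CD14, the monocyte co-receptor for endotoxin (2.85 ± 0.57), S100A9 (2.55 ± 0.53) and TGFBI (2.54 ± 0.41). CD52, a lymphocyte and monocyte surface gene (2.44 ± 0.40), PLBD1 (2.43 ± 0.41) and KCTD12 (2.34 ± 0.42) were also higher. The genes that fell most were the sulfotransferase CHST12 (-2.12 ± 0.30), the selenium carrier SELENOP (-1.90 ± 0.50), CLIP2 (-1.88 ± 0.20), the DNA methyltransferase DNMT3B (-1.74 ± 0.20), the collagen gene COL4A5 (-1.64 ± 0.33) and BAHCC1 (-1.53 ± 0.24).

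Monocyte genes were higher in i16, with 9 of 14 tested members called higher and 12 adjusted over the list alone, among them S100A8 (2.16 ± 0.53), VCAN (2.08 ± 0.48) and CD86 (1.77 ± 0.32). Their median was 1.49 (list adjusted p = 6.76e-12, but adjusted p = 0.11 with an estimated correlation). Of 12 HLA class II genes 8 rose, also 8 adjusted over the list alone, with HLA-DPB1 at 1.72 ± 0.36 and HLA-DPA1 at 1.71 ± 0.41. As a list, HLA class II genes had an adjusted p = 2.5e-09, and an adjusted p = 0.134 with an estimated correlation. Of 13 myeloid transcription factors 5 rose and 1 fell (6 and 1 adjusted over the list alone), with KLF4 at 1.85 ± 0.45, CEBPD at 1.45 ± 0.30, IRF8 at 1.23 ± 0.31 and MYB at -0.53 ± 0.14. This list had an adjusted p = 0.00633 and an adjusted p = 0.14 with an estimated correlation. Immediate early genes were called up with 3 of 14 higher (4 adjusted over the list alone), such as ZFP36 (1.02 ± 0.23) and JUNB (0.90 ± 0.24), at an adjusted p = 0.0016 and an adjusted p = 0.458 with an estimated correlation. Interferon response genes were called up with 2 of 17 higher, also 2 adjusted over the list alone, OAS1 (1.15 ± 0.28) and OAS2 (0.80 ± 0.18), at an adjusted p = 0.00283 and an adjusted p = 0.6 with an estimated correlation. Without 1 i16 array their median fell from 0.35 to 0.17 and the list was not called by camera (adjusted p = 0.0563). The HLA class I and antigen processing genes had a median of 0.23 with 0 of 11 members called either way, also 0 adjusted over the list alone, at an adjusted p = 0.0109 and an adjusted p = 0.548 with an estimated correlation. Of 17 megakaryocyte and platelet genes 4 fell, also 4 adjusted over the list alone, with ITGA2B at -1.01 ± 0.22. As a list, megakaryocyte and platelet genes had an adjusted p = 0.0212, and an adjusted p = 0.442 with an estimated correlation. MN1, a coactivator whose excess drives myeloid leukemia in mice (2.25 ± 0.26), BAALC (1.26 ± 0.29) and NPR3 (1.03 ± 0.31) were the 3 of 17 stem and progenitor markers that rose, and 5 rose adjusted over the list alone. That list and the azurophil granule genes (4 of 12 higher, also 4 adjusted over the list alone, with MPO at 1.70 ± 0.45) were each called up at an adjusted p = 0.0376, with adjusted p = 0.6 and adjusted p = 0.586 with an estimated correlation. Both of these calls ended with arrays scaled to a common median. The reference for the granule genes holds M7, at a list mean of 9.84. The i16 mean of 12.14 lay below PML (12.86) and near AE (12.03), N (12.06) and MLL (11.94). HOXB2 (1.57 ± 0.39) and SPARC, a matrix protein (2.00 ± 0.31), were the called members of the HOXB and stromal lists, which were not called in i16.

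In i16, 584 genes were higher and 478 lower, of which 200 and 40 by at least 2-fold, and the split was 639 and 265 with arrays scaled to a common median. The count of 1062 became 1870 with estimated array weights and 514 with all other arrays pooled as the reference. The call of the megakaryocyte and platelet genes ended without the arrays that stood apart. Without the 2 arrays that did not match their label 1217 genes were called in i16, and the call of the azurophil granule genes ended.

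The PML samples carried high MEG3, an imprinted long noncoding RNA, at 4.96 ± 0.34 above the other groups (adjusted p = 1.8e-23, mean 12.10 ± 1.89 SD, n = 7). STAB1, a scavenger receptor (4.45 ± 0.53), PTGDS, a prostaglandin D synthase (3.89 ± 0.41), CPA3, a mast cell carboxypeptidase (3.85 ± 0.68), and IGFBP2, which binds insulin-like growth factors (3.19 ± 0.61), followed in all 7 arrays above the median of every other group. MMP2, a matrix protease (2.94 ± 0.37), and FGF13 (2.91 ± 0.29) were also higher. Of 12 azurophil granule genes 6 rose and 1 fell, also 6 and 1 adjusted over the list alone, with ELANE, neutrophil elastase, at 3.61 ± 0.66, CST7 at 3.02 ± 0.43, MPO, myeloperoxidase, at 3.01 ± 0.65, and LYZ, lysozyme, at -1.66 ± 0.41. As a list, azurophil granule genes had an adjusted p = 0.0181, and an adjusted p = 0.547 with an estimated correlation. Of 12 HLA class II genes 9 fell, and 11 adjusted over the list alone, with HLA-DRA at -3.06 ± 0.54, HLA-DPA1 at -2.86 ± 0.59 and CD74, the invariant chain, at -2.70 ± 0.44. Their median was -1.84 (list adjusted p = 2.55e-09, but adjusted p = 0.134 with an estimated correlation).

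Of 14 monocyte genes 7 fell in PML, also 7 adjusted over the list alone, with S100A8 at -3.57 ± 0.76, S100A9 at -3.06 ± 0.76 and CD14 at -2.67 ± 0.81. As a list, monocyte genes had an adjusted p = 3.3e-04, and an adjusted p = 0.547 with an estimated correlation. ARHGAP4 (-3.04 ± 0.20, adjusted p = 6.1e-24), CRIP1 (-2.98 ± 0.62) and KCTD12 (-2.96 ± 0.60) completed the largest falls. Of 17 stem and progenitor markers 4 fell and 2 rose (6 and 2 adjusted over the list alone), with NPR3 at -2.89 ± 0.45, CD34 at -2.10 ± 0.50 and FLT3, a receptor kinase, at 1.19 ± 0.37. As a list, stem and progenitor markers had an adjusted p = 0.0497, and an adjusted p = 0.65 with an estimated correlation. Proliferation genes were called down with 6 of 22 lower, also 6 adjusted over the list alone, such as MCM2 (-0.85 ± 0.23) and MCM4 (-0.82 ± 0.22), at an adjusted p = 0.00174 and an adjusted p = 0.724 with an estimated correlation. Interferon response genes were called down with 4 of 17 lower and 1 higher, also 4 and 1 adjusted over the list alone, with OAS1 at -1.38 ± 0.41 and XAF1 at 1.11 ± 0.34 (list adjusted p = 0.0281, and adjusted p = 0.733 with an estimated correlation). F3, the tissue factor that starts clotting, was 1.91 ± 0.27 higher and its inhibitor TFPI -1.48 ± 0.39 lower. CD3D, a T cell receptor subunit, was 1.53 ± 0.46 higher. Neither the coagulation and fibrinolysis list nor the T and NK cell list was called in PML. By its mean, the coagulation and fibrinolysis list (8.67 in PML) lay within the range of the groups, from 8.45 in misc to 8.93 in i16. The fusion partners RARA (0.40 ± 0.28, adjusted p = 0.33) and the gene PML (0.24 ± 0.14, adjusted p = 0.24) were not called with the probe sets that stood for them. Of the 7 kept probe sets of the gene PML 1 was called higher (0.45 ± 0.15, adjusted p = 0.021 over 13881 probe sets).

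In PML, 1004 genes were higher and 880 lower, of which 255 and 247 by at least 2-fold. With arrays scaled to a common median the split was 523 and 1247, and the median log2 fold change of all genes was -0.082 in place of 0.05. The PML arrays had a median correlation with the other arrays of 0.802 and a median log2 3' to 5' ratio of GAPDH of 0.177, against -0.0444 over all arrays. The 3 PML arrays that stood apart had higher means than the other 4 of B cell genes (8.68 to 9.33, against 7.42 to 7.80), erythroid genes (11.51 to 12.24, against 8.43 to 10.98) and T and NK cell genes (9.10 to 9.40, against 7.76 to 8.90). Their spiked-in cre control was brighter (log2 signal 16.19 to 16.42, against 14.26 to 15.71), and their 50 brightest probe sets held 20.4% to 21.8% of the signal, against 9.52% to 14.3%. Their log2 3' to 5' ratio of GAPDH, also used to pick arrays that stood apart, was higher (0.75 to 1.32, against -0.11 to 0.18). Without the 10 arrays that stood apart, 3 of them PML, 620 genes were called, the 16 largest changes given here were still called (smallest size 2.76 log2), and the proliferation call ended. The stem and progenitor and interferon calls ended with arrays scaled to a common median.

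The MLL samples carried high CES1, a carboxylesterase of monocytes and liver (2.69 ± 0.42, adjusted p = 1.7e-06, mean 10.05 ± 2.55 SD, n = 15). KCNE5, a potassium channel subunit (2.40 ± 0.53), LAMP5 (2.29 ± 0.40), the lectin gene LGALS1 (2.28 ± 0.44), the cation channel TRPM4 (2.25 ± 0.33) and DACH1, a developmental transcription factor (2.23 ± 0.35), followed. By mean, KCNE5 in MLL (10.29) lay near PML (9.9). Of the 15 MLL arrays, 10 lay above the median of every other group for CES1, and 9 each for KCNE5 and LAMP5. The homeobox cofactors PBX3 (2.11 ± 0.32) and MEIS1 (1.82 ± 0.30), which bind DNA together with HOX proteins, were higher, while MEIS2 (-0.75 ± 0.26) and TGIF1 (-0.52 ± 0.18) were lower. The list of 6 TALE cofactors was called in no group (in MLL 2 higher and 2 lower, 2 and 3 adjusted over the list alone, adjusted p = 0.408). CAPG (2.07 ± 0.26), CX3CR1, the fractalkine receptor (2.00 ± 0.45), and ITGAX, the CD11c integrin (1.93 ± 0.31), were also higher. The genes that fell most were ITM2A (-3.09 ± 0.42), CYTL1 (-2.52 ± 0.46), MAN1A1 (-2.25 ± 0.35), CPA3 (-2.11 ± 0.49), TRH (-2.05 ± 0.43) and SPARC (-2.02 ± 0.32, and -0.35 in its other probe set). The TRH mean in MLL (6.57) lay near the lowest of the other groups (6.72), and its reference holds AE, at a mean of 12.11.

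Stem and progenitor markers were lower in MLL, with 10 of 17 called lower and 1 higher, and 12 and 4 adjusted over the list alone. They included NPR3 (-2.12 ± 0.32), KIT (-1.93 ± 0.38) and CD34 (-1.33 ± 0.36), against FLT3 at 0.93 ± 0.26. The list median was -1.19 (adjusted p = 4.84e-05, but adjusted p = 0.189 with an estimated correlation). Monocyte genes were called up with 3 of 14 higher, also 3 adjusted over the list alone, among them LILRB2 (1.61 ± 0.42) and CD86 (1.21 ± 0.33), at an adjusted p = 4.86e-04 and an adjusted p = 0.547 with an estimated correlation. Immediate early genes were called down with 4 of 14 lower (6 adjusted over the list alone), such as EGR3 (-0.70 ± 0.18) and IER2 (-0.60 ± 0.17), at an adjusted p = 6.78e-04 and an adjusted p = 0.396 with an estimated correlation. Inflammatory chemokines and cytokines also shifted down, with 4 of 11 lower (6 adjusted over the list alone), such as PTGS2, the inducible cyclooxygenase (-1.30 ± 0.32), and CXCL2 (-1.26 ± 0.31). That list had an adjusted p = 0.00436 and an adjusted p = 0.288 with an estimated correlation. Of 18 T and NK cell genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with CD3D at -1.39 ± 0.33 and NKG7 at 1.60 ± 0.25. As a list, T and NK cell genes had an adjusted p = 0.00596, and an adjusted p = 0.586 with an estimated correlation. Of 12 erythroid genes 2 fell, also 2 adjusted over the list alone, the globin genes HBD (-1.75 ± 0.52) and HBB (-1.07 ± 0.31). As a list, erythroid genes had an adjusted p = 0.0121, and an adjusted p = 0.729 with an estimated correlation. Of 13 myeloid transcription factors 4 rose and 1 fell (5 and 1 adjusted over the list alone), with CEBPA at 1.25 ± 0.26 and WT1 at -1.38 ± 0.33. As a list, myeloid transcription factors had an adjusted p = 0.0497, and an adjusted p = 0.378 with an estimated correlation. Of 17 megakaryocyte and platelet genes 2 fell, also 2 adjusted over the list alone, with ITGA2B at -0.85 ± 0.23. As a list, megakaryocyte and platelet genes had an adjusted p = 0.0461, and an adjusted p = 0.547 with an estimated correlation.

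KMT2A itself, the gene read as rearranged in MLL, was lower at -0.80 ± 0.13 (adjusted p = 1.7e-06), and 2 of its 6 probe sets were called lower, with the most variable one at -0.14 and not called. Among the other fusion partners in MLL, MYH11 was -0.90 ± 0.17, CBFB 0.43 ± 0.12, MRTFA 0.50 ± 0.11 and the gene PML -0.31 ± 0.10. The MYH11 reference holds i16, at a mean of 9.28. The calls of MYH11 and CBFB ended with all other arrays pooled as the reference (-0.77 and 0.42), and those of MRTFA and PML with the most variable probe set (0.02 and -0.78). In MLL, 576 genes were higher and 591 lower, of which 122 and 110 by at least 2-fold, with 648 and 402 when arrays were scaled to a common median and 582 genes called with the other arrays pooled. Without misc in the reference the calls of the myeloid transcription factors and the megakaryocyte genes ended.

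**Figure D3:**
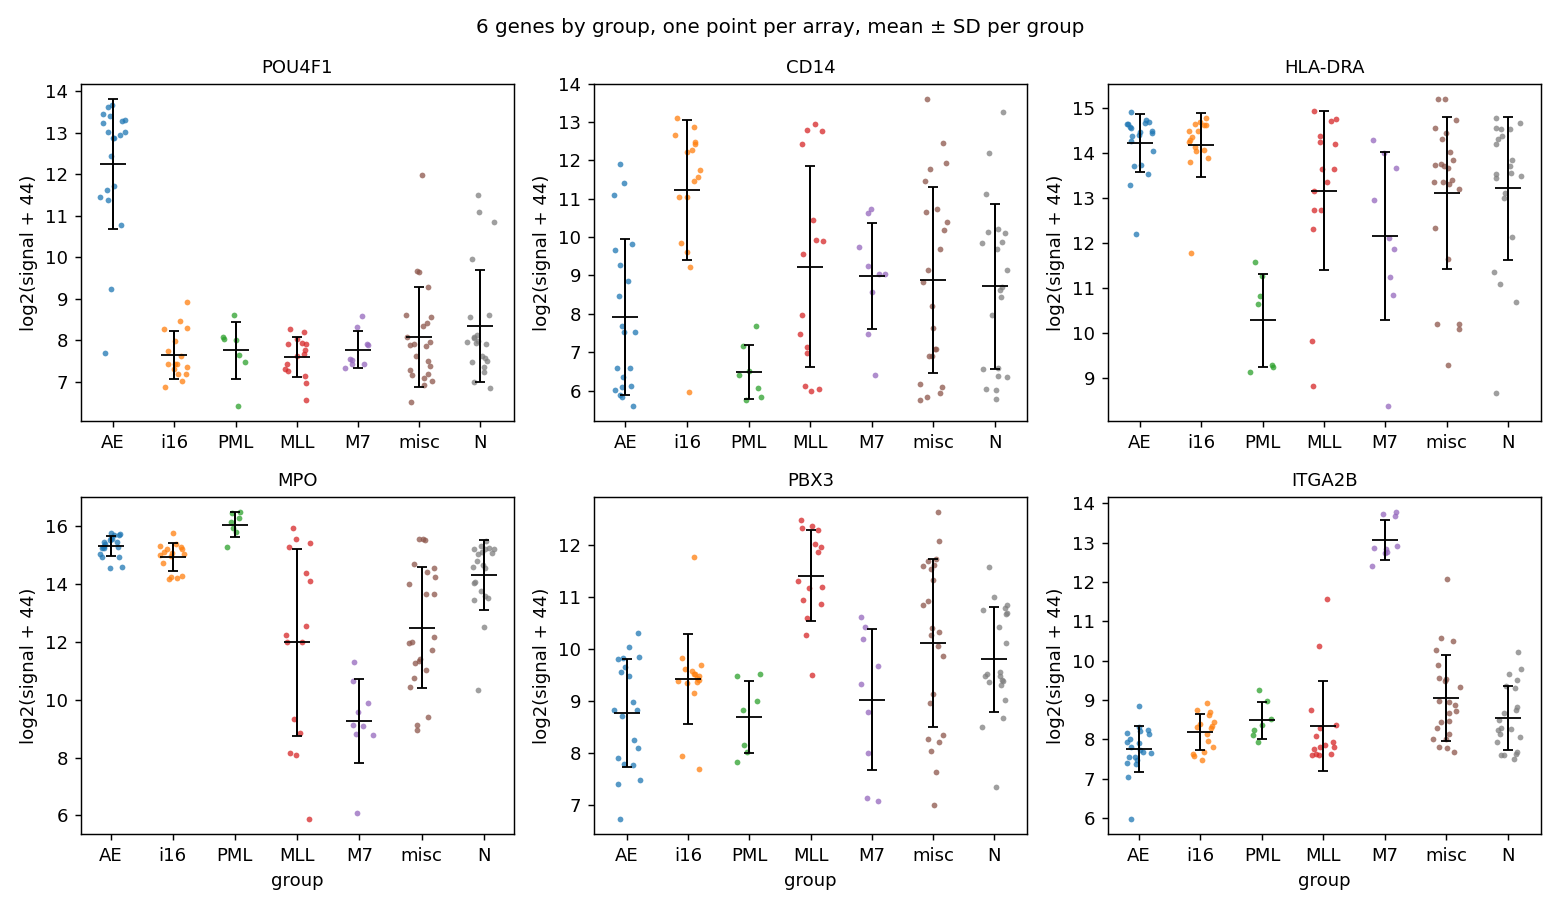
Level of 6 genes that stood out in 1 or more groups (y axis, log2 of signal plus 44), with 1 point per array by group (x axis) and mean ± SD as bars. The mean of ITGA2B was 13.08 in M7 and at most 9.05 in the other groups, and MPO ran from a mean of 9.26 in M7 to 16.07 in PML.

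The M7 samples carried high ITGA2B, the platelet fibrinogen receptor subunit, at 4.68 ± 0.28 above the other groups (adjusted p = 2.6e-27, mean 13.08 ± 0.51 SD, n = 9). BEX3 (4.57 ± 0.53), LAPTM4B (4.48 ± 0.40), PROS1, the anticoagulant protein S (3.37 ± 0.26), and ALDH1A1, a retinaldehyde dehydrogenase (2.93 ± 0.34), followed. FHL2 (2.92 ± 0.37), SERPINI1 (2.91 ± 0.29), the gap junction gene GJA4 (2.84 ± 0.18), RHAG, a red cell membrane gene (2.73 ± 0.54), and PDZD8 (2.72 ± 0.38) were also among the largest rises. Of 17 megakaryocyte and platelet genes 6 rose, and 9 adjusted over the list alone, with GP1BA at 2.29 ± 0.18 and GFI1B at 2.16 ± 0.37. As a list, megakaryocyte and platelet genes had an adjusted p = 2.61e-06, but an adjusted p = 0.0662 with an estimated correlation. Of 12 azurophil granule genes 8 fell, also 8 adjusted over the list alone, with MPO at -4.93 ± 0.58 (adjusted p = 2.7e-11), AZU1 at -4.71 ± 0.53 and ELANE at -4.57 ± 0.59. Their median was -2.34 (list adjusted p = 1.39e-06, but adjusted p = 0.107 with an estimated correlation). CFD, complement factor D (-4.20 ± 0.45), FLT3 (-3.49 ± 0.33) and RNASE2, an eosinophil ribonuclease (-3.47 ± 0.39), were also lower.

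Of 13 myeloid transcription factors 6 fell in M7 and 1 rose (7 and 1 adjusted over the list alone), with CEBPA, which directs granulocyte fate, at -3.34 ± 0.32, GFI1 at -2.52 ± 0.36 and WT1 at 1.36 ± 0.41. As a list, myeloid transcription factors had an adjusted p = 3.19e-04, and an adjusted p = 0.0662 with an estimated correlation. TAL1 (2.28 ± 0.37) and GATA2 (2.12 ± 0.43), regulators of stem cells and of the erythroid and megakaryocyte lines, rose, while the stem and progenitor list, with 4 higher and 4 lower, also 4 and 4 adjusted over the list alone, was not called (adjusted p = 0.708). Proliferation genes rose, with 12 of 22 higher and 16 adjusted over the list alone, such as CCNB1 (0.88 ± 0.20) and TOP2A (0.82 ± 0.25), at an adjusted p = 2.76e-06 and an adjusted p = 0.547 with an estimated correlation. Of 18 T and NK cell genes 6 rose and 1 fell, also 6 and 1 adjusted over the list alone, with TRBC1, a T cell receptor constant gene, at 1.57 ± 0.46, GNLY, granulysin, at 1.49 ± 0.39, and NKG7 at -1.22 ± 0.31. As a list, T and NK cell genes had an adjusted p = 0.0373, and an adjusted p = 0.729 with an estimated correlation. Of 12 B cell genes 3 rose (4 adjusted over the list alone), with VPREB3 at 1.41 ± 0.33 and TCL1A at 1.28 ± 0.30. As a list, B cell genes had an adjusted p = 0.0227, and an adjusted p = 0.586 with an estimated correlation. Of 17 interferon response genes 6 rose, also 6 adjusted over the list alone, with IFI27 at 1.74 ± 0.51 and IFI44L at 1.69 ± 0.57. As a list, interferon response genes had an adjusted p = 0.038, and an adjusted p = 0.746 with an estimated correlation. The HLA class II list was called down, with CD74 (-1.10 ± 0.40) and CIITA (-0.90 ± 0.34) the 2 of 12 lower members, also 2 adjusted over the list alone, at an adjusted p = 0.0355 and an adjusted p = 0.729 with an estimated correlation. Among the fusion partners, MLLT3 (0.92 ± 0.22) and CBFB (0.51 ± 0.14) were higher and MRTFA (-0.66 ± 0.14) and RUNX1T1 (-0.54 ± 0.17) lower. With the most variable probe set, RUNX1T1 turned to 0.59, and MLLT3 (0.61) and MRTFA (-0.43) were not called, and the CBFB call ended with all other arrays pooled (0.47).

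In M7, 1030 genes were higher and 886 lower, of which 257 and 231 by at least 2-fold, with 1375 and 608 when arrays were scaled to a common median. Of the 9 M7 arrays 2 stood apart by a high 3' to 5' ratio, and without the arrays that stood apart the T and NK, B cell and interferon calls ended. With the stricter filter on dim probe sets the HLA class II call ended.

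**Figure D4:**
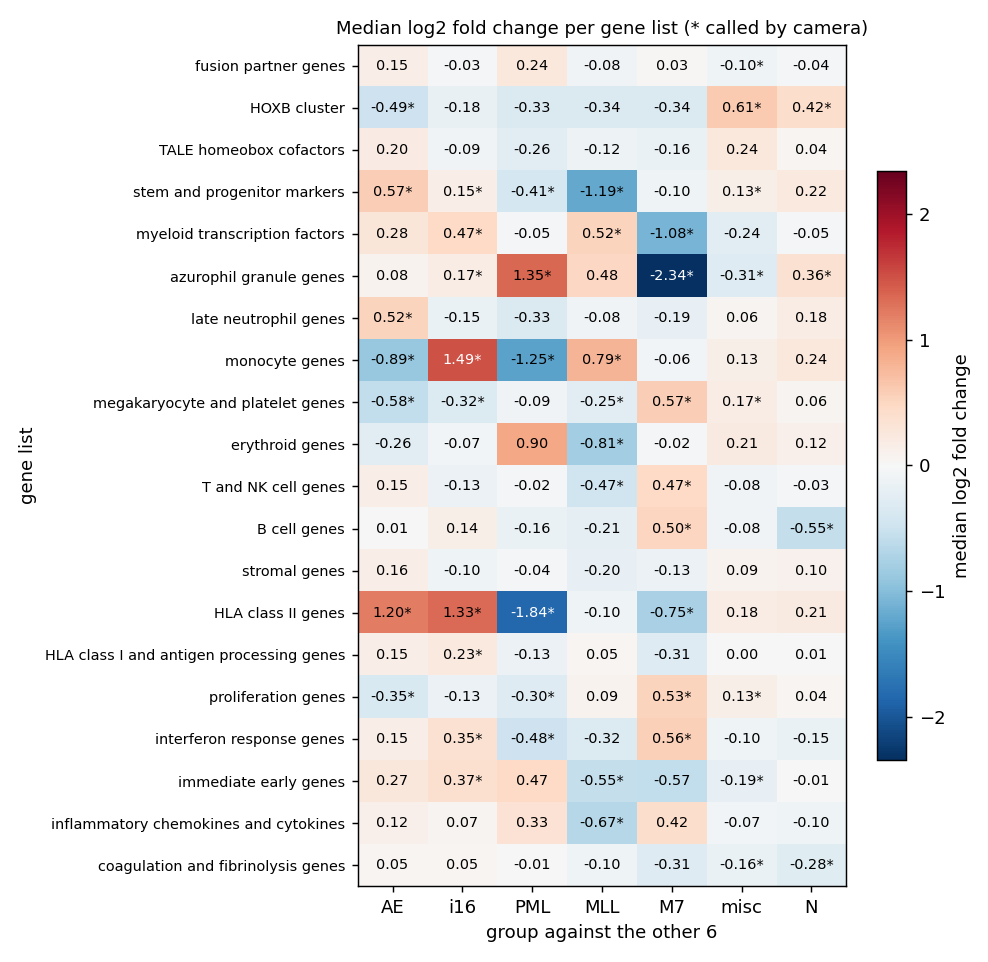
Median log2 fold change of the tested members of each gene list (y axis) in each group against the other 6 (x axis), in color and as a number, with an asterisk where camera with its preset correlation called the list at an adjusted p under 0.05. HLA class II genes run from 1.33 in i16 to -1.84 in PML, and azurophil granule genes from 1.35 in PML to -2.34 in M7.

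The misc samples, whose code names no lesion, had 79 genes called. PPBP, a platelet chemokine (1.72 ± 0.34, adjusted p = 0.0017, mean 9.14 ± 1.95 SD, n = 23), AKR1C3 (1.35 ± 0.35), TESC (1.06 ± 0.24), C11orf21 (0.99 ± 0.15, adjusted p = 5.9e-06), PLCB2, a phospholipase (0.87 ± 0.15), and ARHGAP4 (0.82 ± 0.12) were higher. Some of these did not set misc apart from every group. By mean, C11orf21 (10.92) lay level with MLL (10.90), PLCB2 (10.10) with i16 (10.09) and ARHGAP4 (10.05) with N (10.03). AKR1C3 (10.10) lay below AE (10.23), while PPBP and TESC (10.11) lay above the next group, N (8.51 and 9.91). KCNE5 (-1.63 ± 0.45, adjusted p = 0.049), the growth factor CLEC11A (-1.52 ± 0.28), S100A10 (-1.46 ± 0.34) and WFDC1 (-1.15 ± 0.25) were lower. The misc mean of KCNE5 (6.84) lay above the lowest of the other groups (6.53), and its reference holds MLL (10.29) and PML (9.9). WFDC1 (6.86) lay near the lowest other mean (7.04). CLEC11A (10.69) and S100A10 (10.53) lay below every other group, the lowest of which had 11.1 and 11.17. The HOXB genes, homeobox factors active in early blood progenitors, were higher as a list, with 3 of 7 called higher and 6 adjusted over the list alone. Called were HOXB6 (1.61 ± 0.32), HOXB5 (0.70 ± 0.16) and HOXB3 (0.61 ± 0.16). Without the filter on dim probe sets another HOXB6 probe set took its place and gave -0.08 ± 0.12. Their list was called at an adjusted p = 2.5e-09, and at an adjusted p = 0.0368 with an estimated correlation. Azurophil granule genes were called down, with ELANE (-1.95 ± 0.40) the 1 of 12 that fell, and 2 adjusted over the list alone, at an adjusted p = 1.07e-04 and an adjusted p = 0.189 with an estimated correlation.

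Further lists were called in misc with few members called. SPINK2 (1.89 ± 0.44) was the 1 of 17 stem and progenitor markers that rose (3 adjusted over the list alone), at a list adjusted p = 0.0136 and an adjusted p = 0.547 with an estimated correlation. PPBP was the 1 of 17 megakaryocyte and platelet genes that rose (5 adjusted over the list alone), at a list adjusted p = 0.0121 and an adjusted p = 0.376 with an estimated correlation. Of 22 proliferation genes 0 were called, also 0 adjusted over the list alone, with a median of 0.13, an adjusted p = 0.00505 and an adjusted p = 0.729 with an estimated correlation. EGR1 (-1.10 ± 0.29) was the 1 of 14 immediate early genes that fell (2 adjusted over the list alone), at a list adjusted p = 0.00417 and an adjusted p = 0.547 with an estimated correlation. Of 13 coagulation and fibrinolysis genes 2 fell (3 adjusted over the list alone), S100A10 and SERPINE2 (-0.71 ± 0.16), at a list adjusted p = 0.0043 and an adjusted p = 0.0877 with an estimated correlation. With the probe sets that stood for the genes, MYH11 (-0.71 ± 0.14) was the 1 of 11 fusion partners called lower, also 1 adjusted over the list alone, at a list adjusted p = 0.0437 and an adjusted p = 0.161 with an estimated correlation. The reference for MYH11 holds i16, at a mean of 9.28, and the misc mean of 6.53 lay near those of AE (6.51), MLL (6.37) and N (6.63). Against a reference that holds AE, 3 of 4 RUNX1T1 probe sets were called lower in misc (-1.14, -0.96 and -0.49), as they were in i16, MLL and N. In misc, 43 genes were higher and 36 lower, of which 9 and 9 by at least 2-fold. With all other arrays pooled as the reference 3 genes were called, PPBP and CLEC11A keeping their calls among the 10 genes with the largest changes, and without the arrays that stood apart the calls of the fusion partner and proliferation lists ended.

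In the N samples HOXB6 was 1.52 ± 0.34 higher (adjusted p = 0.008, mean 7.99 ± 2.05 SD, n = 21), and the HOXB list was called up with 1 of 7 members higher and 3 adjusted over the list alone (list adjusted p = 3.05e-06, and adjusted p = 0.0877 with an estimated correlation). BAHCC1 (1.09 ± 0.22), ADA, adenosine deaminase (1.08 ± 0.26), LSP1 (1.02 ± 0.26), ADGRE1 (0.77 ± 0.20) and FUT4, which makes the CD15 antigen (0.68 ± 0.16), were also higher, and so was CEBPA (1.09 ± 0.23). The N means of HOXB6 (7.99), LSP1 (10.33) and ADGRE1 (9.58) lay just below those of misc (8.07, 10.35 and 9.63). FUT4 (11.15) lay level with AE (11.14) and BAHCC1 (10.82) with PML (10.77), while ADA (10.91) lay above the next group, misc (10.41). MTSS1 (-1.36 ± 0.23, and -0.10 in its other probe set), HSPG2, perlecan (-1.31 ± 0.24, and -0.50), CHD7 (-0.94 ± 0.19) and MYH11 (-0.59 ± 0.15) were lower. The reference for MYH11 holds i16, at a mean of 9.28, and the N mean lay near those of AE, MLL and misc given above. The heat shock gene HSPB1 fell by 1.00 ± 0.26 (log2). B cell genes had a median of -0.55, with 0 of 12 called over all genes and 6 lower adjusted over the list alone (list adjusted p = 1.58e-06, and adjusted p = 0.134 with an estimated correlation). Azurophil granule genes had a median of 0.36, with 0 of 12 called and 2 higher adjusted over the list alone (list adjusted p = 0.0214, and adjusted p = 0.547 with an estimated correlation), a call that ended without misc in the reference and without the 2 arrays that did not match their label. The reference for the granule genes holds M7, at a list mean of 9.84. The N mean of 12.06 lay near those of i16 (12.14), AE (12.03) and MLL (11.94). Coagulation and fibrinolysis genes had a median of -0.28, with 0 of 13 called, also 0 adjusted over the list alone (list adjusted p = 0.0253, and adjusted p = 0.161 with an estimated correlation). In N, 24 genes were higher and 27 lower, of which 6 and 5 by at least 2-fold. The count of 51 became 0 with all other arrays pooled as the reference, 210 with estimated array weights and 103 without the 2 arrays that did not match their label. Without the filter on dim probe sets another HOXB6 probe set gave 0.11.

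**Figure D5:**
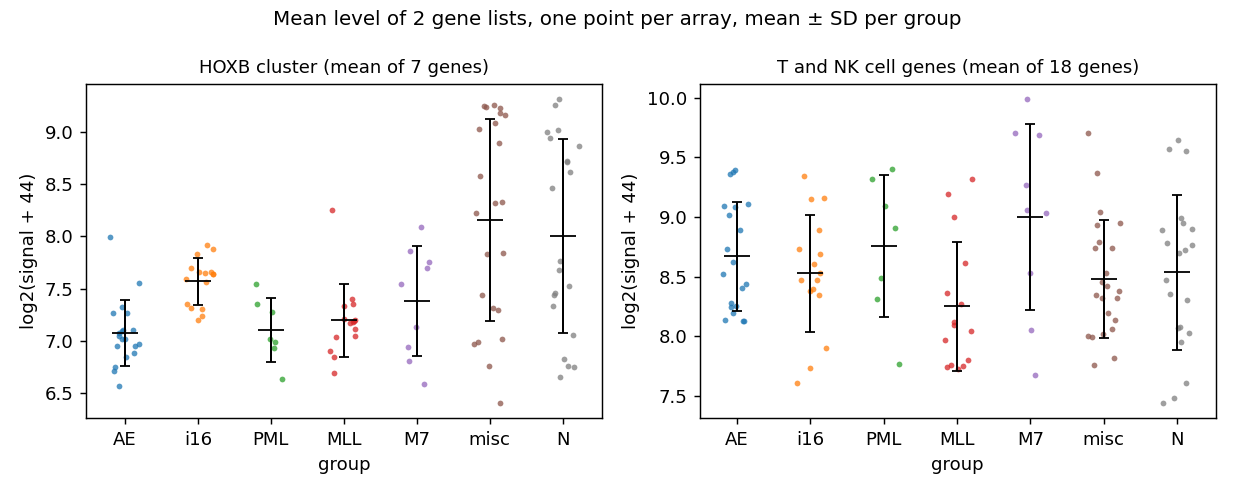
Mean level per array of 7 HOXB genes and of 18 T and NK cell genes (y axis, log2 of signal plus 44), with 1 point per array by group (x axis) and mean ± SD as bars. HOXB means above 8.25, the highest in AE, i16, PML, MLL and M7, were found in 12 of 23 misc and 10 of 21 N arrays.

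Set directly against i16, the other core-binding factor group, AE had higher POU4F1 (4.59 ± 0.36, adjusted p = 2.4e-19), ROBO1 (3.71 ± 0.31), TRH (2.88 ± 0.51), PRAME (2.69 ± 0.38) and CAV1, caveolin (2.55 ± 0.28). It had lower LGALS2 (-3.84 ± 0.53), PLBD1 (-3.42 ± 0.50), CD14 (-3.31 ± 0.69), the kinase SGK1 (-3.21 ± 0.52) and RNASE6 (-3.16 ± 0.56). Of 14 monocyte genes 12 were lower in AE, and 13 adjusted over the list alone, with a median of -2.02 (list adjusted p = 5.72e-13 over the 20 lists of this comparison, but adjusted p = 0.107 with an estimated correlation). MEIS1 was -2.00 ± 0.35 and HOXB2 -2.59 ± 0.48 in AE relative to i16. Of the fusion partners, MYH11 was -2.77 ± 0.20, CBFB 1.16 ± 0.14, RUNX1T1 1.13 ± 0.17, KMT2A 0.63 ± 0.15 and MLLT10 0.35 ± 0.11. This RUNX1T1 value is that of the probe set with the highest mean on the log2 scale, and the 1 with which all AE arrays lay above the others had means of 10.04 in AE and 6.02 in i16. In all 498 genes were higher and 525 lower, of which 117 and 244 by at least 2-fold, with 260 and 672 when arrays were scaled to a common median and 1698 genes called with estimated array weights.

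Between misc and N, limma called 0 of 9369 genes, with 401 at an unadjusted p under 0.05 and a smallest adjusted p of 0.723. As a list, the azurophil granule genes were lower in misc than in N, with a median of -0.65, 0 of 12 members called over all genes and 2 lower adjusted over the list alone. ELANE was -1.86 ± 0.51 and MPO -1.83 ± 0.50 in misc relative to N, and the list had an adjusted p = 6.18e-09, but an adjusted p = 0.0525 with an estimated correlation. B cell genes had a median of 0.39 (list adjusted p = 0.00293, and adjusted p = 0.993 with an estimated correlation), and immediate early genes one of -0.19 (list adjusted p = 0.0151, and adjusted p = 0.993 with an estimated correlation), with 0 members of either called over all genes or adjusted over the list alone. The 10 stromal genes were called as a list in none of the 9 comparisons, with medians from -0.20 in MLL to 0.17 in AE against i16.

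Some list calls rest on single arrays. With each of the 111 arrays left out in turn, 18 of the 50 list calls ended without 1 or more arrays of the group itself. In AE these were the late neutrophil genes, whose median fell from 0.52 to 0.25 without 1 array (adjusted p = 0.449), and the HOXB cluster. In i16 they were the interferon response genes (0.35 to 0.17 without 1 array, adjusted p = 0.0563), the azurophil granule genes (0.17 to 0.06) and the stem and progenitor markers. In PML they were the proliferation genes (-0.30 to -0.11 without 1 array, adjusted p = 0.126) and the azurophil granule, interferon response and stem and progenitor lists. In M7 the calls of the B cell genes (0.50 to 0.23), HLA class II genes (-0.75 to -0.48), interferon response genes (0.56 to 0.41) and T and NK cell genes (0.47 to 0.37) each ended without any 1 of 3 arrays. The others were the myeloid transcription factors and megakaryocyte and platelet genes in MLL, the proliferation genes (0.13 to 0.08) and fusion partners in misc, and the azurophil granule genes in N.

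Some of these values rest on the probe set that stood for the gene. Of 110 values of genes named by the size of their change, 28 had several kept probe sets, and in 8 of these another gave under 1/1.5 of the log2 fold change. Of these 8, LAT2, SPARC, MTSS1 and HSPG2 are given with both values above. For the other 4 the smallest value was -1.70 for S100A8 in PML, -1.20 for MAN1A1 in MLL, 1.75 for RHAG in M7 and 0.39 for FUT4 in N. Of the list members and fusion partners given above, besides those stated there with other probe sets, another probe set was that much smaller and not called for KMT2A (0.00), CIITA (0.32) and BIRC5 (-0.22) in AE, NPR3 (0.00) and SPARC (0.51) in i16, and NPR3 (-0.35) and TFPI (-0.36) in PML. The same held for CBFB (0.20), the gene PML (0.25), WT1 (-0.62) and CD86 (0.54) in MLL, and for GATA2 (-0.02), TRBC1 (0.66), CIITA (-0.11) and TOP2A (0.30) in M7. In misc it held for EGR1 (-0.55), and in AE against i16 for KMT2A (-0.06) and MLLT10 (-0.22). In 40 of the 110 values the dimmer side had a mean below 7.69, the lowest array median on this scale, so the sizes of these changes depend on the pseudocount.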

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

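Of the tests in this part, those with other splits of the samples, the 3' to 5' covariate and the sets holding all PML arrays that stood apart, the PML count and the granule genes with the cell list means as covariates, the T and NK cell genes without the arrays that stood apart, and those of array scaling and of a faulty probe set were chosen only after the result was seen.

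In the groups of 7 and 9 arrays, the highest and lowest array were compared with the spread of the group, for the 16 genes with the largest changes under the naming rule, the called fusion partners and the 20 tested lists. Of these 76 tests 6 found an array far from the rest, where chance gives about 1 in 20. This count is not far above that rate, and the tests share arrays and genes, so chance may account for it. In PML, the highest S100A9 array (11.7, the nearest at 9.57) had a gap of 0.613 of the group's range. The lowest PML array of the interferon response genes (7.87, the nearest at 8.31) had a gap of 0.624. In M7, the lowest MPO array (6.09, the nearest at 8.78) had a gap of 0.516 of the range. RUNX1T1 had 0.512 in M7 (6.62, the nearest at 7.89). The lowest M7 array of the stem and progenitor markers (8.41, the nearest at 9.04) had a gap of 0.535. For the proliferation genes in M7 the gap was 0.494 (9.16, the nearest at 10.16).

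Chance in how the samples were grouped was tested with 100 splits into groups of the same sizes for each count, the real one included. All labels of the 111 arrays were shuffled, or those of the 2 groups in a direct comparison. Only the real split gave as many genes in AE (1369, highest other split 8), i16 (1062 and 14), PML (1884 and 106) and MLL (1167 and 1). The same held for M7 (1916 and 189), misc (79 and 3), N (51 and 9), AE against i16 (1023 and 4) and the F test (4083 and 6). This argues against chance for the grouping as a whole. Shuffling all labels breaks every group at once, so it does not test 1 group, such as misc or N, alone. With the other arrays pooled as the reference, 3 genes were called in misc and 0 in N. For misc against N, where 0 genes were called, all 100 splits reach that count by construction, so the splits say nothing about chance. The highest of the others called 282, and their median was 0. A split that calls so many can point to a structure among these samples other than the 2 groups, or to genes that vary together, and neither was tested.

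The count of 1884 genes in PML fell to 620 without the arrays that stood apart. Having fewer PML arrays is not the whole cause: 5 of the 35 sets of 4 PML arrays called as few genes as the set without those arrays, which the bound set beforehand would have read as enough, but that bound was too lax, because the 4 sets holding all 3 arrays that stood apart called 1825 to 2304 genes with the same number of arrays. With the T and NK and erythroid means as covariates 1864 genes were called, which argues against T, NK or red cells in the PML arrays as the whole cause. With the 3' to 5' ratio as a covariate 1487 genes were called, 1311 of them also called without it. The 3 arrays that stood apart had a higher log2 3' to 5' ratio of GAPDH (0.75 to 1.32, against -0.11 to 0.18 on the other 4). A covariate with 1 slope over all arrays may not remove such an effect, so it does not decide on uneven RNA quality. The lowest count of 1825 in sets holding those 3 arrays, against 470 to 769 in sets with 1 of them, is consistent with many PML calls resting on these arrays. They also had higher B cell means (8.68 to 9.33, against 7.42 to 7.80 on the other 4) and erythroid means (11.51 to 12.24, against 8.43 to 10.98), a brighter spiked-in cre control and more signal in the 50 brightest probe sets, so RNA quality, B cells or other cells not covered by these lists, handling and the leukemia itself stay open.

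In M7, azurophil granule genes were lower and T and NK cell genes higher by camera with its preset correlation, neither being called with an estimated correlation (adjusted p = 0.107 and adjusted p = 0.729), and the T and NK call ended without any 1 of 3 arrays. Dilution by T, NK or red cells does not account for the lower granule genes, whose median was -2.33 with the T and NK cell and erythroid means as covariates, against -2.34 without. Across the 9 M7 arrays the 18 T and NK cell genes rose and fell together, with a median pairwise r of 0.583 over 153 pairs of genes, against a 95th percentile of 0.0771 among 10000 random lists. The other groups were not tested in this way, and marker genes of a cell type may move together there too. This therefore does not say why M7 was higher, and a larger share of T and NK cells in part of the samples stays open. Among the T cell genes CD3D had a mean of 10.77 ± 1.90 SD and TRBC1 of 10.78 ± 1.59 SD in M7, leukemic cells can express some of these genes, and no sort of the cells is given. Without the arrays that stood apart the list median was 0.35 against 0.47, which argues against these arrays as the whole cause although the call ended.

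CBFB was lower in i16 and KMT2A in MLL, the genes that the codes of these groups were read to name. Loss of a segment spanning most of the 20 nearest tested genes, shared by the group, is argued against, since these had a median of -0.03 for CBFB and for KMT2A. They ran from -0.49 to 1.89 around CBFB and from -1.39 to 0.81 around KMT2A, with 1 called lower and 1 higher each. A median over both sides and the whole group cannot see a smaller or one-sided loss, or one in few samples. Array scaling does not either, with CBFB at -1.15 and KMT2A at -0.75 when arrays were scaled to a common median. A faulty probe set is argued against for CBFB, with 2 of 2 probe sets called lower, but cannot be told apart from a lower level for KMT2A, with 2 of 6, since the probe sets may read different parts of the transcript. The rearrangement of each gene stays open as the biological explanation, and the position of each probe set relative to a break was not tested.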

How the results depend on the processing

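Leaving out the 10 arrays that stood apart, the 2 that did not match their label, or each array in turn (which ended 18 of 50 list calls) was chosen after seeing the data, and the other alternatives here beforehand. Of 3104 values of named genes and of fusion partners in each group under the alternatives, 3020 kept their side of the threshold, 61 lost the call, 22 gained one and 1 reversed. Of 2360 list values these were 2170, 153, 36 and 1. Direction was compared only for values called in the main fit, so values called in neither fit count as kept whatever their direction. With every probe set, the one with the smallest p stood for the gene. The reversals were RUNX1T1 in M7 (0.59 with the most variable probe set, against -0.54) and the erythroid list in MLL (median 0.06 with the T and NK and erythroid means as covariates, which remove the means of the T and NK and erythroid lists themselves, so that the loss of both calls in MLL is by construction). The count in N (51) was 94 with a pseudocount equal to the median, 79 with quantile normalization, 87 with the stricter filter, 93 with every probe set, 210 with estimated array weights, 0 with the other arrays pooled, 170 without misc in the reference, 100 with the T and NK and erythroid covariates and 103 without the 2 arrays that did not match their label. With estimated array weights the counts were also 1870 in i16, 125 in misc and 1698 in AE against i16. With the other arrays pooled they were 514 in i16, 582 in MLL and 3 in misc. Pooling changed the reference and the spread together, so the falls cannot be credited to the reference alone. Without the arrays that stood apart 620 genes were called in PML. With an estimated correlation 1 list was called in place of 50, and with fry 37. Apart from the covariates' own lists, the cause was not tested. With the replicate block the count in misc was 51 against 79, and every other count stayed within 1.5 times. The numbers share no more than a label: 256 pairs of arrays with the same number had a median correlation of their deviations of -0.00372 (40 over 0.1), and 6 of 111 arrays correlated best with their own number. Dim probe sets limit what can be seen, since 13881 of 19034 passed the filter.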

Other observations

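The HOXB counts and the test of labels were made after the values were seen. The mast cell and chromosome tests were set before their results were seen, though KIT was already known to be higher in AE.

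The HOXB list, called up in misc and, with the preset correlation only, in N, was not raised evenly over their arrays. The highest mean of 7 HOXB genes on any AE, i16, PML, MLL or M7 array was 8.25, and 12 of 23 misc and 10 of 21 N arrays lay above it. In N the array means ran from 6.65 to 9.32 with the widest gap between 7.77 and 8.47, and in misc from 6.40 to 9.26 with the widest gap between 7.44 and 7.83. HOXB6 lay above 9.34, its highest level in the other 5 groups, on 10 misc and 9 N arrays. Another HOXB6 probe set, which did not pass the filter, gave -0.08 in misc and 0.11 in N.

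By MYH11 and CBFB together 2 arrays, 1 in i16 and 1 in N, did not match their group's label. By the mean of 98 other genes, those with the smallest p in i16 in a fit without these arrays, both also lay on the wrong side of the midpoint, as did 7 of the other arrays. As a hypothesis, a wrong label of these arrays, such as a swap, may lie behind this, with 2 of 2 placed so by the other genes. A lesion that the labels do not name stays open beside it.

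Since the tryptase genes and HPGDS were higher in AE, a list of 10 other genes of mast cells was tested there, of which 8 were measured. Of these, 3 were called higher: KIT (1.47 ± 0.34, adjusted p = 8.7e-04), HPGD (1.32 ± 0.35, adjusted p = 0.0039) and IL1RL1 (0.86 ± 0.20, adjusted p = 7.4e-04). FCER1A was at 1.16 ± 0.43 (adjusted p = 0.052), CPA3 at 1.12 ± 0.43 (adjusted p = 0.069), HDC at 0.48, GATA2 at 0.36 and SIGLEC6 at 0.07, none of these 5 called. The bound of 3 set beforehand was reached only with KIT, and without it 2 genes were called higher, so the list does not decide whether mast cells or their genes are raised in AE. KIT and GATA2 are also stem and progenitor markers, and leukemic cells can express them.

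Gain or loss of a chromosome in part of a group's samples might shift its genes together. Of the tests of 22 autosomes in 7 groups over 9030 genes, 0 were called by camera with the preset or with an estimated correlation, 6 and 1 had an unadjusted p under 0.05, and the smallest adjusted p was 0.987. The written bound read a count of 0 as evidence against such shifts, which was wrong, since a p over the threshold does not limit a shift. The largest chromosome median was 0.14 in size, so gains in a few samples of a group remain open.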
